A study of Anopheles gambiae with 8 samples.

How the data were processed

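RNA was sequenced from 8 pools of 5 whole adult females of Anopheles gambiae, strain G3. Per the labels' protocols, mosquitoes were reared at 28°C under 16 h of light and 8 h of dark with 8% fructose, and 5-day-old females were offered a blood meal for 10 min, starting 4 h after lights on. Some females were placed at 9°C for 20 min before feeding and others were not; the labels do not say which libraries these went into. Control females were held in a similar chamber with water. Fed and control animals were collected together 3 h later, after chilling for 20 min, and stored in groups of 5. Total RNA was extracted with Trizol, treated to remove DNA, and selected for poly-A, and libraries with fragments of 200 bp were prepared with an Illumina TruSeq RNA kit and sequenced as paired reads of 50 nt. The labels do not state that the kit marks strand, so reads of overlapping genes on opposite strands were not separable here.

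The authors deposited 1 transcript table per library, whose records carry FPKM (mapped fragments normalized to transcript length and to the library's total) and read coverage, per the file headers and attribute fields. The submitters' processing notes name CASAVA 1.8.0a16, TopHat (a spliced-read aligner) and Cufflinks (a program that estimates transcript abundance), without versions for the last ones. The genome build and annotation release are not given in the sources used here. Each table listed the same 15310 transcripts of 13460 genes, 1250 of them with more than 1 transcript. No pair of libraries held identical values. Because FPKM is a normalized estimate and not a count, no count-based test was used. Cufflinks divides fragments among overlapping transcripts by a likelihood model, so closely related gene copies and overlapping genes carry uncertainty that the FPKM does not show. In 30 genes a value of 0 in 1 library stood beside at least 20 FPKM in another, and 27 of these genes had a longest transcript under 200 nt, shorter than the stated fragments.

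Depth was estimated from the files by multiplying each transcript's coverage by its length, and dividing by the bases in a pair of reads of 50 nt. These are estimates of fragments assigned to transcripts, not counts of reads sequenced. The totals ran from 13278596 to 17477288 in the NBF group and from 13051846 to 15386891 in the BF3h group. A gene value of 0.45 to 0.55 FPKM, near the filter, rested on a median of 11.2 estimated fragments (quartiles 6.73 and 16.9), so values at this level are imprecise. The 10 most abundant genes of a library took 6.96 to 8.56% of the aligned bases.

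Libraries were grouped by the titles and descriptions in the labels. FPKM values of the transcripts of a gene were summed, and each library was divided by a median-of-ratios size factor (0.95 to 1.07). Genes with at least 0.5 FPKM in at least 4 of the 8 libraries were kept, and 0.5 was added before taking log2. A fold change is therefore on the log2(FPKM + 0.5) scale, which understates changes of genes with low values. The groups were compared with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes moderation with a mean-variance trend), and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Each replicate was a separate pool of females, so the p-values measure the spread between these pools, which were collected in 1 experiment as far as the labels say. On simulated data with 200 changed genes among 10305, the test recovered 65% of genes changed by a log2 of 1 and 94% of those changed by a log2 of 2, with 11 false calls. The changed genes were drawn from those with a mean above 2 FPKM, and the noise was independent between genes and libraries. These rates therefore do not cover genes near the filter, effects shared within a library, or data in which a larger share of genes changed.

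Gene lists were fixed before the data were examined, as were the test, the filter, the rule for named genes and most of the alternatives. A list's members were to be found by gene identifier, symbol or description. The files hold identifiers only, and 0 of the identifiers were found in the RefSeq gene table of assembly idAnoGambNW_F1_1, so membership rests on the identifiers written into the lists beforehand from general knowledge, which neither the files nor that table can check. This left 45 genes in 11 lists. The lists of cuticular proteins (R&R family and other families), muscle, odorant receptors, gustatory and ionotropic receptors, odorant-binding proteins, immune genes, cytochrome P450, glutathione S-transferases and carboxylesterases, heat shock proteins, ribosomal proteins, ribosome biogenesis, oxidative phosphorylation, proteasome, histones, ecdysone response, immediate early genes and mitochondrial transcripts were not analysed here, nor were the parts of the 11 lists that depended on names. Lists with at least 3 tested members were tested with camera (preset correlation 0.01, Benjamini-Hochberg over the lists), beside camera with an estimated correlation and fry, from limma. Camera compares a list with the other genes, whereas fry tests the list by itself. The genes named in the text were the 12 with the greatest increase and the 12 with the greatest decrease among called genes with at least 5 FPKM in 1 group and no overlap between groups, and from each list up to 4 called members, or the most abundant members where none was called. As the files do not pair identifiers with names, 2 genes that rose and 2 that fell outside the lists are printed. Of all called genes, 240 (13.5%) overlap another gene in position, a share close to that of all tested genes (1250, 12.0%). Such overlap makes the values of these genes uncertain. None of the overlapping genes is among the genes named in the text with their FPKM values. The 4 genes named for transcripts called in opposite directions were not checked for overlap.

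The alternatives were pseudocounts of 0.1 and 1, no filter or a filter of 1 FPKM, FPKM as deposited, quantile normalization, limma without the trend, with array quality weights or with robust moderation, the replicate number as a block, each library left out in turn, transcripts in place of genes, and an estimated correlation in the list test. A removal of each library's trend with transcript length (loess, span 0.5) and a restriction to genes above 0 in every library were added after seeing the data. Neighbouring genes were examined by shuffling the calls over gene positions (10000 shuffles for pairs and 1000 for runs). Calculations outside R used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9; array quality weights used statmod 1.5.0.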

Results

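Gene expression was measured by RNA sequencing in whole adult females of the G3 laboratory strain of Anopheles gambiae, an African malaria mosquito. The females were 5 days old, and each library was made from polyadenylated RNA of a pool of 5 females. The 4 blood-fed libraries (BF3h) were collected 3 h after a blood meal, and the 4 non-blood-fed libraries (NBF) came from control females of the same age that had access to water. The series asks how transcript abundance had changed 3 h after the meal, with particular attention to cuticular proteins. From the coverage in the files, the NBF libraries held an estimated 15208383, 13713650, 17477288 and 13278596 fragments (replicates 1 to 4), and the BF3h libraries 14211032, 14096263, 15386891 and 13051846. Each library listed 13460 genes, of which 11546 to 11730 had a value above 0. Across genes, Spearman's rho was 0.964 to 0.989 between libraries of one group and 0.943 to 0.967 between libraries of different groups. The values below are FPKM after scaling between libraries, given as mean ± SD over the 4 pools of a group. Changes are log2 differences, BF3h minus NBF, on the log2(FPKM + 0.5) scale, with the standard error from limma and p-values adjusted by the Benjamini-Hochberg method. Coordinates are those of the files, whose genome build is not given in the sources used here. The files identify genes by AGAP numbers only and do not pair them with names, so genes are described through the fixed lists they belong to.

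At 3 h after the blood meal, a gene of the yolk and lipid transport list stood far above its level in unfed females, and the chymotrypsins of the gut protease list stood far below theirs. AGAP004203 of the yolk and lipid transport list was at 0.70 ± 0.52 FPKM in NBF and 74.3 ± 38.3 FPKM in BF3h (n = 4 each), a change of 5.91 (SE 0.39, adjusted p = 3.1e-05). AGAP006709, a chymotrypsin of the gut serine protease list, fell from 694 ± 205 to 38.9 ± 15.0 FPKM, a change of -4.16 (SE 0.27, adjusted p = 2.5e-05). Among all genes, 1775 of the 10383 tested passed an adjusted p of 0.05 in limma (17.1%), 784 of them higher and 991 lower in BF3h. Of these, 231 were at least 2-fold higher and 424 at least 2-fold lower, and 74 and 110 differed by at least 4-fold. The median absolute change of the called genes was 0.83. The median signed change of all tested genes was 0.03, a value that the scaling between libraries holds near 0. The 4 BF3h values did not overlap the 4 NBF values in 2460 genes (23.7% of those tested, against 2.86% by chance), which included 1692 of the called genes. Leaving out 1 library, which leaves fewer samples, changed the number of called genes. It was 1154 without NBF replicate 2, 1181 without BF3h replicate 1 and 1104 without BF3h replicate 3, but 1997 without NBF replicate 1. With array quality weights, which let limma count some libraries less, it was 3395.

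**Figure D1:**
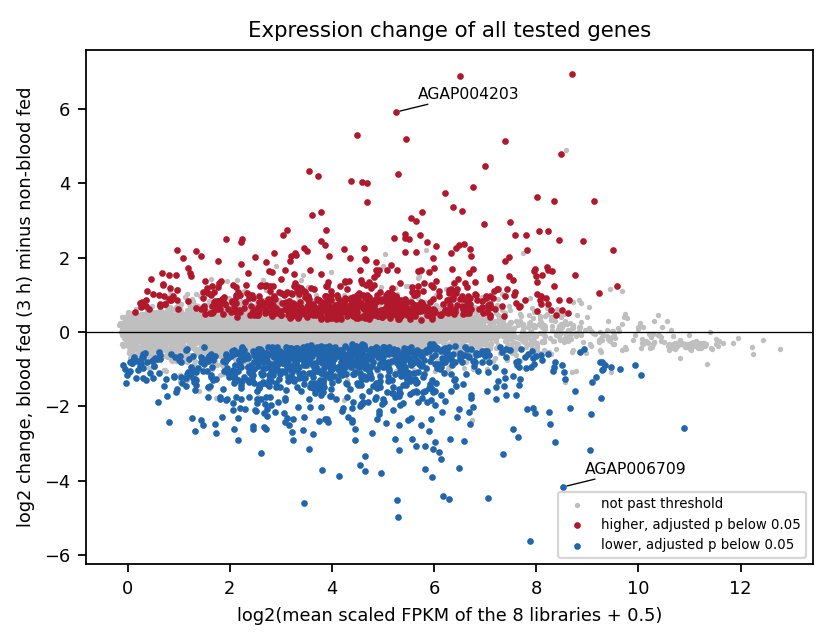
Change in expression of the 10383 tested genes, blood fed minus non-blood fed (log2 scale, vertical axis), against the mean scaled FPKM of the 8 libraries (log2 scale after adding 0.5, horizontal axis). Each point is a gene; red points mark the 784 genes called higher, blue points the 991 called lower, and grey points those not past the threshold.

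The genes that changed most belonged to none of the lists whose members could be identified, apart from AGAP004203 and AGAP006709. The 12 called genes with the greatest increases, chosen by a rule on level and overlap, rose by 4.03 to 6.94, and the corresponding 12 decreases ran from -3.74 to -5.61. AGAP006187 (chromosome arm 2L, 27931493 to 27932433, plus strand) rose from 5.12 ± 1.97 to 822 ± 596 FPKM, a change of 6.94 (SE 0.51, adjusted p = 4.6e-05). Its BF3h libraries ranged from 241 to 1647 FPKM, each above the highest NBF value of 7.89 FPKM. AGAP004350 (2R, 54940341 to 54942685, plus strand) rose from 1.04 ± 0.40 to 180 ± 43.4 FPKM, a change of 6.86 (SE 0.23, adjusted p = 1.4e-06). AGAP011939 (3L, 35407855 to 35408974, minus strand) fell from 462 ± 56.1 to 9.21 ± 2.94 FPKM, a change of -5.61 (SE 0.20, adjusted p = 1.4e-06). AGAP012394 (3L, 41710048 to 41711592, minus strand) fell from 75.8 ± 17.4 to 2.06 ± 1.08 FPKM, a change of -4.96 (SE 0.28, adjusted p = 1.1e-05). What these 4 genes encode is not stated in the files. The estimated fragments in the library with fewest were 40.1 for AGAP006187, 27.5 for AGAP004350, 127 for AGAP011939 and 18.3 for AGAP012394. Another of the 12 decreases lies close to AGAP012394, at 41712157 to 41713673 on the plus strand of 3L (change -4.49). Reads shared between these close genes were not examined, so the values of AGAP012394 are uncertain to that extent.

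The gut serine protease list holds trypsins and chymotrypsins, enzymes that digest the proteins of a meal in the midgut. All 10 members were tested; 1 rose, 3 fell and 6 did not pass the threshold. The 3 that fell were the 3 chymotrypsins, which lie between 37118475 and 37128206 on 2L. Beside AGAP006709, AGAP006711 fell from 946 ± 147 to 113 ± 52.7 FPKM, a change of -3.18 (SE 0.33, adjusted p = 0.00029), and AGAP006710 fell from 111 ± 17.7 to 13.6 ± 7.71 FPKM, a change of -3.15 (SE 0.36, adjusted p = 0.00055). Among the 7 trypsins, which lie between 8624615 and 8635726 on 3R, changes ranged from -0.85 to 2.31 with a median of 1.10, and 1 passed the threshold. That gene, AGAP008293, rose from 20.6 ± 11.4 to 110 ± 66.8 FPKM, a change of 2.31 (SE 0.47, adjusted p = 0.0099); its BF3h libraries gave 53.3, 54.6, 149 and 185 FPKM. The number of members past the threshold was 5 when p-values were adjusted over the list alone. As a set the list did not differ from other genes in camera (adjusted p = 0.73, and 0.95 with an estimated correlation), and its median change (0.42) and mean change (-0.42) differed in sign, camera's direction being down. In fry, the p-value was 0.115 for movement in one direction and 1.4e-07 for change in either direction. Reads shared between these similar, neighbouring genes could not be separated here, so the values of single members are uncertain to that extent.

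**Figure D2:**
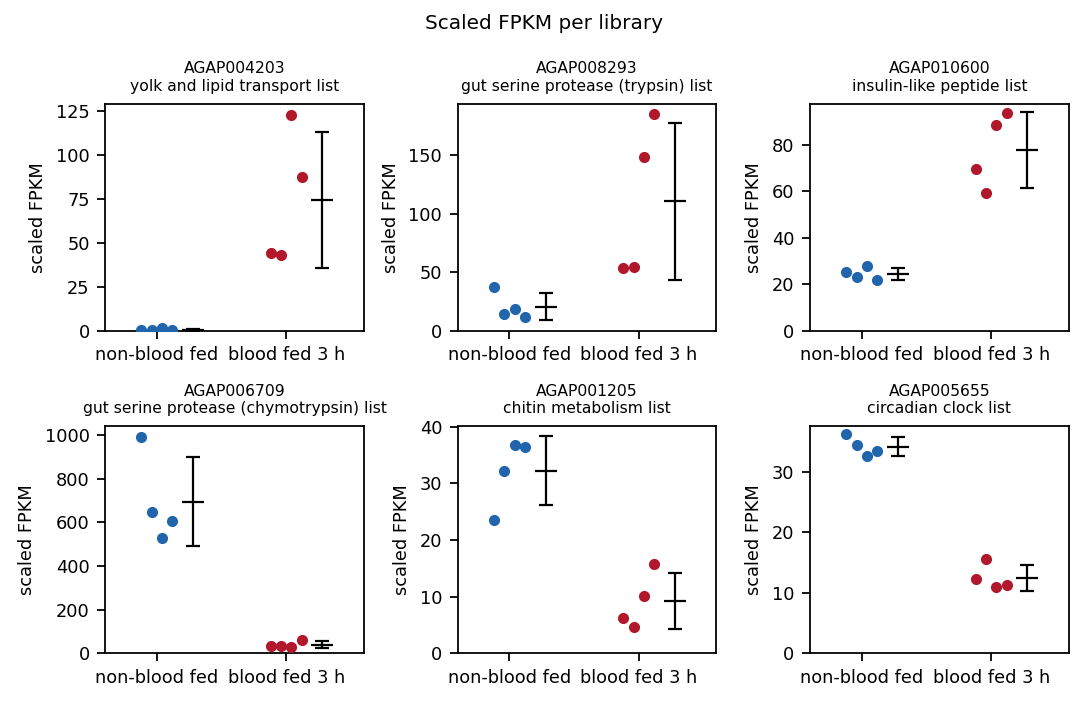
Scaled FPKM of 6 list genes past the threshold in each library (vertical axis, linear), with 4 non-blood-fed pools in blue and 4 blood-fed pools in red; the horizontal bar is the group mean and the whiskers are 1 SD. In each panel the 4 blood-fed values lie wholly above (AGAP004203, AGAP008293, AGAP010600) or wholly below (AGAP006709, AGAP001205, AGAP005655) the 4 non-blood-fed values.

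Yolk protein precursors and lipid carriers of the hemolymph make up the yolk and lipid transport list, of which 2 members were identified and tested. AGAP004203 (2R, 51786017 to 51792488, plus strand) rose, with BF3h libraries at 44.1, 42.8, 123 and 87.4 FPKM and the NBF library with most at 1.45 FPKM. Because the NBF values are close to the pseudocount, its log2 change depended on that choice and was 6.60 with a pseudocount of 0.1; it was 5.23 with array quality weights. The other member, AGAP001826, named after its values were seen, was at 321 ± 153 FPKM in NBF and 596 ± 279 FPKM in BF3h and did not pass the threshold (change 0.87, adjusted p = 0.17). Its change was 0.22 with array quality weights, and its adjusted p ranged from 0.066 to 0.686 over the alternatives. In this list 1 member passed adjusted over the list alone. In the germline and ovary list neither member passed: AGAP008578 gave 244 ± 28.8 and 202 ± 44.6 FPKM (change -0.30, adjusted p = 0.31), and AGAP006098 gave 26.2 ± 5.37 and 31.3 ± 5.95 FPKM (change 0.25, adjusted p = 0.43). The list of male markers was meant as a check for male RNA. Of its 3 members, 2 were tested and neither passed. A comparison of the groups cannot show male RNA present in both groups or in only 1 pool. Adjusted over the list alone, 0 members passed in the germline and ovary list and 0 in the male list. AGAP009099 was at 0.84 ± 0.64 FPKM in NBF and 0.77 ± 0.43 FPKM in BF3h, and AGAP008622 at 0.67 ± 0.13 and 0.61 ± 0.12 FPKM. These means are near the filter, where values are imprecise.

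Chitin is a component of both the cuticle and the peritrophic matrix, the layer that forms around a blood meal in the midgut. Of the 2 members of the chitin metabolism list, 1 was expressed highly enough to be tested. This gene, AGAP001205 (2R, 1501390 to 1514018, plus strand), fell from 32.2 ± 6.14 to 9.18 ± 4.96 FPKM, a change of -1.88 (SE 0.33, adjusted p = 0.0047). The single identified member of the peritrophic matrix list, AGAP006795, was at 925 ± 222 FPKM in NBF and 490 ± 280 FPKM in BF3h. It did not pass the threshold over all genes (change -1.07, SE 0.37, adjusted p = 0.087). With 1 member, adjustment over the list alone changes nothing and leaves the unadjusted limma p of 0.018. AGAP006795 passed over all genes with quantile normalization (adjusted p = 0.037), with array quality weights (0.0068) and without BF3h replicate 4 (0.017). Its adjusted p ranged from 0.0068 to 0.207 over the alternatives.

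Genes of the circadian clock, the molecular feedback loop that keeps daily time, fell or did not pass the threshold. Of the 7 members of this list, 3 fell, 0 rose and 4 did not pass; 4 passed adjusted over the list alone. AGAP005655 fell from 34.2 ± 1.56 to 12.5 ± 2.14 FPKM, a change of -1.43 (SE 0.13, adjusted p = 0.00015). AGAP004261 fell from 16.4 ± 1.10 to 10.8 ± 1.67 FPKM (change -0.59, adjusted p = 0.014), and AGAP001958 fell from 40.3 ± 2.26 to 26.8 ± 1.22 FPKM (change -0.58, adjusted p = 0.0036). The list was the 1 of 5 large enough to test that passed in camera with a preset correlation (adjusted p = 0.034), with a median change of -0.53. The alternatives in which it did not pass included an estimated correlation (adjusted p = 0.352) and leaving out NBF replicate 3 (adjusted p = 0.091), NBF replicate 4 (0.106), BF3h replicate 1 (0.061) or BF3h replicate 2 (0.051), and its adjusted p ranged from 0.0063 to 0.352 over the alternatives. In fry on the main settings, the unadjusted p-value for the clock list was 0.00076 for movement in one direction and 6.1e-07 for change in either direction. Both groups were collected at the same time, per the labels.

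**Figure D3:**
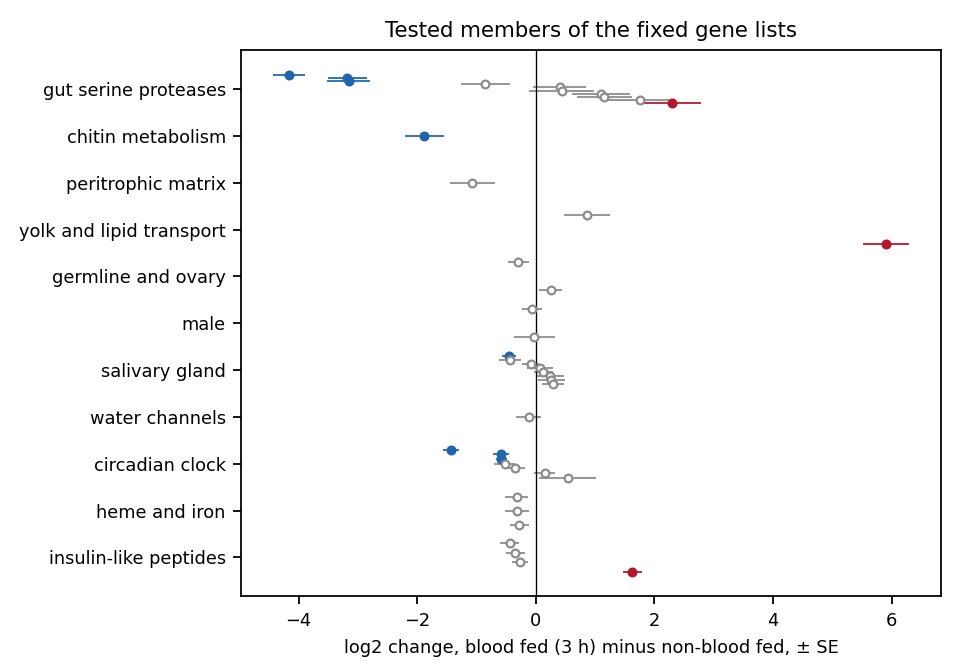
Log2 change in expression, blood fed minus non-blood fed (horizontal axis), of each tested member of the 11 fixed lists with identified members (vertical axis). Points are genes and whiskers are 1 standard error from limma; filled red points rose, filled blue points fell, and open points did not pass the threshold.

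Insulin-like peptides are secreted hormones that act on metabolism and egg development in mosquitoes. Of the 6 members of that list, 4 were tested. Over all genes, 1 rose and 3 did not pass. Adjusted over the list alone 2 passed, the gene that rose and a member with a negative change (-0.44, limma p adjusted over the list = 0.046). The latter was at 2.28 FPKM in NBF and 1.56 FPKM in BF3h. It lies within the position of another member on the same strand, so its value is uncertain. AGAP010600 (3L, 7093689 to 7094422, plus strand) rose from 24.5 ± 2.61 to 77.7 ± 16.2 FPKM, a change of 1.63 (SE 0.16, adjusted p = 0.00025). The list's median change was -0.31 and its mean 0.14, camera's direction was down (adjusted p = 0.88, and 0.95 with an estimated correlation), and fry gave p = 0.29 for one direction and p = 0.0092 for either direction. In the salivary gland list, 1 of 8 members fell, 7 did not pass, and 1 passed adjusted over the list alone. That member, AGAP001374, was at 83.1 ± 8.15 FPKM in NBF and 60.6 ± 7.37 FPKM in BF3h (change -0.45, SE 0.13, adjusted p = 0.036). The alternatives that lost its call included FPKM as deposited (adjusted p = 0.067), quantile normalization (0.090), removal of the length trend, an alternative added after seeing the data (0.075), and leaving out any of NBF replicate 2 (0.115), NBF replicate 3 (0.101), BF3h replicate 1 (0.081), BF3h replicate 3 (0.112) or BF3h replicate 4 (0.076), and its adjusted p ranged from 0.0068 to 0.115 over the alternatives. The salivary list as a set gave an adjusted p of 0.90 in camera (0.95 with an estimated correlation), with a median change of 0.10 and a mean of 0.002 against a camera direction of down.

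None of the 3 members of the heme and iron list passed the threshold, over all genes or adjusted over the list alone. AGAP002465 was at 815 ± 181 FPKM in NBF and 650 ± 131 FPKM in BF3h (change -0.32, adjusted p = 0.31), and AGAP002464 at 798 ± 148 and 645 ± 156 FPKM (change -0.32, adjusted p = 0.33). The set gave an adjusted p of 0.39 in camera (0.95 with an estimated correlation), and fry gave p = 0.13 for one direction and p = 0.46 for either direction. The single water channel identified, AGAP008842, was at 34.1 ± 8.81 FPKM in NBF and 30.6 ± 4.52 FPKM in BF3h (change -0.12, adjusted p = 0.74) and did not pass; with array quality weights its change was -0.34 and its adjusted p 0.047, the lowest of the alternatives, whose highest was 0.942. Cuticular protein genes, named in the title of the series, were not analysed here as a group, because no member could be identified from the gene identifiers.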

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

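The removal of the length trend, its test as the whole cause for NBF replicate 1, and the tests of depth, of random placement and of same-strand pairs described here were chosen after the results were seen. Dixon's test at the 95% level was applied to 56 sets of 4 libraries. Of these, 48 were for the 24 genes that the report names by identifier with their FPKM values, in each of the groups. The other 8 were for 4 library measures (estimated fragments, the sum of FPKM, the share of the 10 most abundant genes, and the FPKM-weighted transcript length). In 4 of the 56 sets, all of them for genes, 1 library was set apart from the other 3; chance alone sets apart about 5% of such sets. In AGAP006795 of the peritrophic matrix list, NBF replicate 1 was at 1255 FPKM and the other NBF libraries at 782 to 849 FPKM. In AGAP001826 of the yolk and lipid transport list, NBF replicate 3 was at 548 FPKM and the other NBF libraries at 229 to 276 FPKM. In AGAP004350, one of the genes that rose most, BF3h replicate 2 was at 115 FPKM and the other BF3h libraries at 197 to 208 FPKM. In AGAP006098 of the germline and ovary list, BF3h replicate 4 was at 22.4 FPKM and the other BF3h libraries at 33.5 to 34.8 FPKM.

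The number of genes that differed between fed and unfed females was weighed against chance, transcript length and depth. Of the 35 ways to split the 8 libraries into 4 and 4, 1 gave as many called genes, the real one with 1775. The highest of the others gave 1, which argues against chance assignment of the libraries. With 35 splits the test cannot exclude chance. The other splits mix fed and unfed libraries, so a difference between fed and unfed adds to the spread within their groups and lowers their calls. After each library's trend with transcript length was removed, 95.0% of the called genes stayed called in the same direction, which argues against that trend as the source of most calls. The mean estimated fragment total differed by -732971 (BF3h minus NBF) and the totals of the groups overlapped, so depth did not separate the groups. Feeding itself and anything else that differed between fed and control females remain open as sources of the difference and were not tested apart; the labels do not tie the cold exposure to a group or library.

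NBF replicate 1 stood apart from the other NBF libraries: its mean squared deviation from the mean of the other 3 on the log2 scale was 0.396, against 0.0948, 0.143 and 0.165 for the other libraries measured in the same way, and its deposited FPKM values summed to 681906 against 553753 to 604401. Its estimated 15208383 fragments were not the lowest of the group, which argues against low depth. Across genes, which are not independent replicates, deviations from the group mean had Spearman's rho with transcript length of -0.45, -0.03, 0.35 and 0.42 (NBF replicates 1 to 4), whose opposite signs are partly fixed because the deviations sum to 0 in each gene. Removing the length trend lowered its squared deviation by 21.9%, to 0.309, against 0.0944, 0.124 and 0.138 for the others (after falls of up to 16.5%); this argues against the trend as the whole cause, while a partial share of length stays open, and a difference in the animals of that pool was not tested. Without this library 1997 genes were called, and 90.8% of the 1775 were among them in the same direction.

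Genes that fell lay next to each other more often than random placement gave. Of 10114 adjacent pairs of tested genes, 200 were both called lower, against a mean of 91.2 and a highest value of 130 in 10000 shuffles of the calls (one-sided permutation p = 0.0001, the smallest these shuffles can give), which argues against random placement. Reads shared by overlapping or close genes could give such pairs. For opposite-strand pairs at least 1000 bp apart, 32 were both lower against a shuffled mean of 31.4 (ratio 1.02, permutation p = 0.475). No excess was seen at that distance, so on opposite strands shared reads stay open for the excess among the closer pairs. For same-strand pairs at least 1000 bp apart the ratio was 2.18 (permutation p = 0.0001), which argues against shared reads as the whole source for those. Without the distance limit the ratios were 1.41 on opposite strands and 3.13 on the same strand. Shared reads therefore also stay open for part of the same-strand excess, among the closer pairs. Neither reads shared by near-identical copies further apart nor a biological explanation was tested.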

How the results depend on the processing

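The removal of the length trend and the restriction to genes above 0 in every library were chosen after the results were seen. No called gene was called in the opposite direction under any alternative on genes. Pseudocount, filter, scaling, limma without the trend and robust moderation gave 1706 to 1918 called genes, which held 91.4 to 99.7% of the 1775 in the same direction; transcripts in place of genes gave 1701 calls, and 4 of the 965 genes with 2 or more tested transcripts had transcripts called in opposite directions (AGAP004437, AGAP004592, AGAP006366 and AGAP008940, named after their values were seen). Removing the length trend gave 2043 and requiring values above 0 gave 1776. Array quality weights gave 3395 called genes, 1617 higher and 1778 lower, holding 98.6% of the 1775; the cause was not tested. Leaving out 1 library, which leaves fewer samples, gave 1104 to 1997 called genes and 426 to 970 called higher. The total fell by more than 1.5 times without NBF replicate 2 (1154), BF3h replicate 1 (1181) and BF3h replicate 3 (1104). The number called higher did so without NBF replicate 2 (480), NBF replicate 3 (500), BF3h replicate 1 (519) and BF3h replicate 3 (426). The number of lists past the threshold, 1 with the preset correlation, was 0 with an estimated correlation, 0 with the replicate block, and 0 to 1 when 1 library was left out. The clock list accounts for each of these losses, its adjusted p ranging from 0.0063 to 0.352, with 0.081 under the block. Moderation and weights do not enter camera and say nothing about its stability. With the replicate number as a block, 1314 genes were called, and 70.3% of the 1775 were among them. The correlations of same-numbered libraries' deviations were -0.09, 0.15, 0.20 and -0.12, and 1 of the 4 NBF libraries correlated best with its own number, so the numbers were not taken to pair the libraries. Under the block AGAP001374 had an adjusted p of 0.059, and under the removal of the length trend 0.075. Over all alternatives, 465 results for named genes stayed on their side of the threshold, 4 passed it and 9 lost it. The alternatives for cuticular proteins were not run, since no member was identified. Genes near 0.5 FPKM rested on a median of 11.2 estimated fragments, which limits calls at that level.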

Other observations

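The tests of runs of neighbouring genes and the regions described here were chosen after the results were seen. In 13 regions, at least 4 consecutive tested genes were all called lower, 57 genes in all. Shuffling the calls over positions gave a mean of 0.746 such runs and at most 4. No distance limit was applied to the genes of a run, so reads shared by close neighbours were not tested as a source of these runs. Consecutive genes called higher gave 0 such runs by limma's adjusted p, with a shuffled mean of 0.324. The longest runs had 6 genes each, on 2R from 21045662 to 21067725 and on 3L from 39812373 to 39838568, with a median log2 change of -1.34 in each. The lowest median was in a run of 4 genes on 3R from 10088546 to 10099123, at -2.67, with single genes from -1.79 to -3.41 and all 4 on the plus strand. Another run of 4 genes, all on the plus strand of 3R from 10719260 to 10744793, had a median of -2.07. The files do not say what the genes in these regions encode. Pairs of adjacent genes both called higher numbered 79, against a shuffled mean of 60.2 (one-sided permutation p = 0.0069). Among pairs at least 1000 bp apart this excess did not pass 0.05, with 48 pairs against a shuffled mean of 41.6 on any strand (one-sided permutation p = 0.169) and 27 against 20.9 on the same strand (p = 0.104).

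The counts of called genes were also taken by expression level and chromosome arm, with no test of the differences between these classes. When the tested genes were divided by mean FPKM into 3 groups of equal size, 283 of the called genes in the group of lowest expression fell and 165 rose, and in the group of highest expression 399 fell and 387 rose. The called share was 12.9% in the lowest, 15.6% in the middle and 22.7% in the highest group. By chromosome arm, the called share was 16.8% on 2L, 17.1% on 2R, 16.4% on 3L, 18.3% on 3R and 17.6% on X. On the unplaced sequence, 30 of 264 tested genes fell and 3 rose.

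In a principal component analysis of the tested genes, the component with 50.7% of the variance separated the groups, with NBF libraries at -46.4, -31.0, -24.3 and -24.7 and BF3h libraries at 33.0, 23.8, 37.5 and 32.1. On the component with 18.7% of the variance, the NBF libraries lay at 41.5, -7.06, -22.4 and -26.8 and the BF3h libraries at 0.75, 0.13, 4.27 and 9.66. On the component with 15.6%, the NBF libraries lay at -1.67, -4.44, 12.5 and 0.44 and the BF3h libraries at -18.0, -31.7, 12.5 and 30.4 (replicates 1 to 4). For the BF3h replicates in the same order, list genes chosen after their values were seen gave 305, 237, 564 and 852 FPKM for AGAP006795, 53.3, 54.6, 149 and 185 FPKM for AGAP008293, and 44.1, 42.8, 123 and 87.4 FPKM for AGAP004203. Other list genes gave different orders, such as 12.2, 15.6, 10.96 and 11.2 FPKM for AGAP005655 and 62.1, 70.4, 56.4 and 53.7 FPKM for AGAP001374. The labels mention feeding with and without a preceding cold exposure but do not tie either to a library, so no comparison was made.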
